A study of Homo sapiens with 4 samples.

How the data were processed

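RNA was sequenced from T47D cells, a luminal, oestrogen receptor-positive human breast cancer line established from a pleural effusion, after transfection of a control siRNA or of an siRNA against RBM39. The labels describe 4 libraries, 2 per group, with the letters A and B in each group. The control libraries are titled WT SiRNA, which is taken here to mean a control siRNA. Nothing in the labels says whether the letters stand for separate cultures, paired dishes or different siRNA sequences. Total RNA was purified with a Qiagen kit and made into Illumina libraries, per the labels' protocols.

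The deposited table holds FPKM values, fragment counts scaled to transcript length and library size, computed by the authors, in 1 column for control cells and 1 for RBM39 siRNA cells. Neither column carries a replicate letter, so each is taken as the authors' value for its group; how the 2 libraries of a group were combined is not given in the sources used here. The RBM39 siRNA column is headed with CAPER, a synonym of RBM39 in the RefSeq gene table. CASAVA, TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff 2.2.1 are named in the submitters' processing notes, with the builds hg19 and mm10, and their roles and the annotation are not given in the sources used here. Because the reference annotation at hand is on GRCh38, no coordinates are printed. It was used only for names, gene spans, containment of a gene in another, transcript length and GC content.

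The table had 32648 rows. The 4912 rows without a gene name held 0.946% of the summed control FPKM and 0.404% of the summed RBM39 siRNA FPKM, and were left out. For 552 symbols with more than 1 row, the rows were summed. The 516 rows that join several symbols, whose loci overlap, were kept as 1 item each and were not used for the list members they contain. This left 26161 names, of which 12143 had a mean FPKM of at least 1 over the 2 groups and were compared. Some genes (HLA-B, HLA-C and BOP1 among them) are listed at 0 in both groups under their own symbol, and the cause was not tested.

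The planned tests (limma on log2 values, with camera and fry for gene lists) need values per library and could not be run on 1 value per group. Nor could a paired fit or fits that leave out a library. The plan made before the data were examined said that in this case values would be given without a test, so no p-value, SE or SD is given. Differences are log2(FPKM + 1) in the RBM39 siRNA group minus the same in the control group, a scale that understates the change of low genes; fold values beside FPKM values are plain ratios of the 2 FPKM values. Depth is unknown, because the table gives no counts. The low values do not move in steps: 5.27% of 2487 rows with low values lay within 0.02 log2 units of the commonest ratio between the columns, so whole reads were not recovered and no counting interval is given.

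The 21 gene lists were fixed in the same plan, and the comparison with random lists was chosen after the table was seen, in place of camera and fry. For each list with at least 5 compared members, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was called higher or lower when its median lay above or below the central 95% of these medians. This percentile describes the 2 columns and is no test of the conditions, since genes of a list move together and are not replicates. With 20 lists, about 1 would lie outside by chance if genes were independent. The procedure was tested on simulated data over the 12143 genes. It called 3 of 100 simulated lists of 30 genes with no shift, and 100 of 100 lists with a shift of 0.5. The simulated differences were drawn independently for each gene from a normal distribution. These rates therefore do not hold for real lists, whose genes move together.

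Genes were named by a rule. The first is RBM39, followed by the 10 largest differences upward and 10 downward among compared genes with at least 5 FPKM in the higher group, leaving out small nucleolar, small nuclear and micro RNA genes by symbol. The rule for list members used p-values, so in its place the 2 members with the largest absolute difference were taken, and in a list with 2-fold members in both directions also the largest in the other direction. That replacement, and any other member named, was chosen after the values were seen.

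Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, median-ratio scaling, quantile normalization, and leaving out genes listed at 0 in a group. Those added after the data were seen were the highest row of each symbol, leaving out joined rows, leaving out genes with a span of at most 300 bp, removing a cubic trend in transcript length and GC content (known for 93.2% of the compared genes, from GENCODE release 29 transcripts, with differences limited to 2 log2 units either way in the fit), and a 1.5-fold threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.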

Results

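The transcriptome of T47D cells was compared between cells given a control siRNA and cells given an siRNA against RBM39. RBM39, also called CAPER, is an RNA-binding protein of the spliceosome and a coactivator of the oestrogen receptor and AP-1. The design lists 2 libraries per group, and the values analysed here are the authors' FPKM, 1 per gene and group. There are therefore no replicate values: every difference below is between 2 numbers, its replicate error is unknown, and none was tested. FPKM values summed to 1287781 in the control group and 1522715 in the RBM39 siRNA group. Short genes, with a span of at most 300 bp, held 30.5% and 33.2% of these sums, since short transcripts gain very large FPKM values.

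RBM39 itself was lower in the group that received its siRNA; its level was 92.1 FPKM in control cells and 37.5 FPKM in RBM39 siRNA cells, 40.8% of control or 2.45-fold lower. Of the 12143 genes compared, 1.39% had a lower log2 difference. RBM23, the closest paralogue of RBM39, stood at 19.6 FPKM in control cells and 18.9 FPKM in RBM39 siRNA cells.

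In all, 300 genes were at least 2-fold higher and 325 at least 2-fold lower in RBM39 siRNA cells on the log2(FPKM + 1) scale, together 5.15% of the genes compared. The median difference over all compared genes was 0.01, with quartiles at -0.25 and 0.26. S100A8, a calcium-binding protein of inflamed epithelium and myeloid cells, was at 2.07 FPKM in control and 145 FPKM in RBM39 siRNA cells, a 70.0-fold difference. RSAD2, the antiviral enzyme viperin, was 31.6-fold higher, and KRT17, a stress keratin of basal epithelium, was 31.4-fold higher at 55.4 FPKM. KRT17 has near-identical pseudogene copies, so its level is less certain. The antiviral genes IFIT2, IFIT3 and OASL were 18.3-fold, 16.4-fold and 15.6-fold higher, reaching 219, 415 and 437 FPKM. Complement factor B (CFB) was 17.0-fold higher and the chemokine CCL5 was 15.8-fold higher. The vault RNAs VTRNA1-3 and VTRNA1-2 were listed at 0 in control cells and at 149276 and 24828 FPKM in RBM39 siRNA cells. Both spans are 88 bp, and 29 of the 86 short genes at 5 FPKM or more in a group were listed at 0 in the other.

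Among the 10 largest differences downward, CA9, a carbonic anhydrase induced by hypoxia, went from 15.9 FPKM in control to 1.43 FPKM in RBM39 siRNA cells, 11.1-fold lower. The neuronal enolase ENO2 was 7.52-fold lower, SPAG4 was 7.23-fold lower and ANKRD37, a hypoxia-induced gene, was 4.78-fold lower. TFF3, a secreted trefoil peptide of oestrogen-responsive breast cells, went from 649 to 128 FPKM, 5.09-fold lower. SERPINA6, which encodes corticosteroid-binding globulin, went from 330 to 62.5 FPKM, 5.28-fold lower. The sialyltransferase ST8SIA6 was 7.09-fold lower and the MAP kinase phosphatase DUSP4 was 5.06-fold lower. PRTN3 was low in both groups, at 5.43 and 0.461 FPKM. SCRIB was listed at 25728 FPKM in control and 43.1 FPKM in RBM39 siRNA cells, and a short gene, MIR937 with a span of 86 bp, lies inside it.

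Interferon-stimulated genes were higher as a group in RBM39 siRNA cells. All 33 listed members were compared and all 33 were above control, 20 of them at least 2-fold, with a median log2 difference of 1.35. The medians of all 10000 expression-matched random lists were lower, with 95% of them between -0.20 and 0.09. Beside RSAD2 and IFIT2, the ubiquitin-like protein ISG15 went from 473 to 1694 FPKM and OAS1, which makes the activator of RNase L, from 82.5 to 290 FPKM. The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) were 3.21-fold and 2.60-fold higher. Several members were already abundant in control cells and differed little: IFI6 stood at 2551 and 3161 FPKM, and IFI27 at 2403 and 3027 FPKM. The 9 members at 100 FPKM or more in control had a median difference of 0.84, and the 24 others had 1.45. Markers of blood and endothelial cells stayed low beside this group. Of 17 markers, 15 were under a mean of 1 FPKM, too few being left to place the list among random lists. The macrophage gene CD68 was at 1.65 FPKM in control and 0.787 FPKM in RBM39 siRNA cells, and the pan-leukocyte gene PTPRC was at 0.00315 and 0.00167 FPKM.

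Genes of glycolysis and the hypoxia response were lower as a group. Of 28 compared members, 28 were below control and 21 were at least 2-fold lower, with a median of -1.31 against -0.21 to 0.10 for 95% of random lists. Beside CA9 and ENO2, the most abundant glycolytic transcripts were among them. PGK1 went from 1387 to 363 FPKM, ALDOA from 2096 to 783 FPKM, GAPDH from 2156 to 857 FPKM and LDHA, which converts pyruvate to lactate, from 1133 to 520 FPKM. The glucose transporter SLC2A1 was 2.25-fold lower and the pyruvate dehydrogenase kinase PDK1 was 4.44-fold lower. The muscle isoform PFKM was the member closest to no difference, at 22.8 FPKM in both groups. The 19 glycolytic enzymes and transporters had a median of -1.25 and the 9 other hypoxia genes -1.55.

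**Figure D1:**
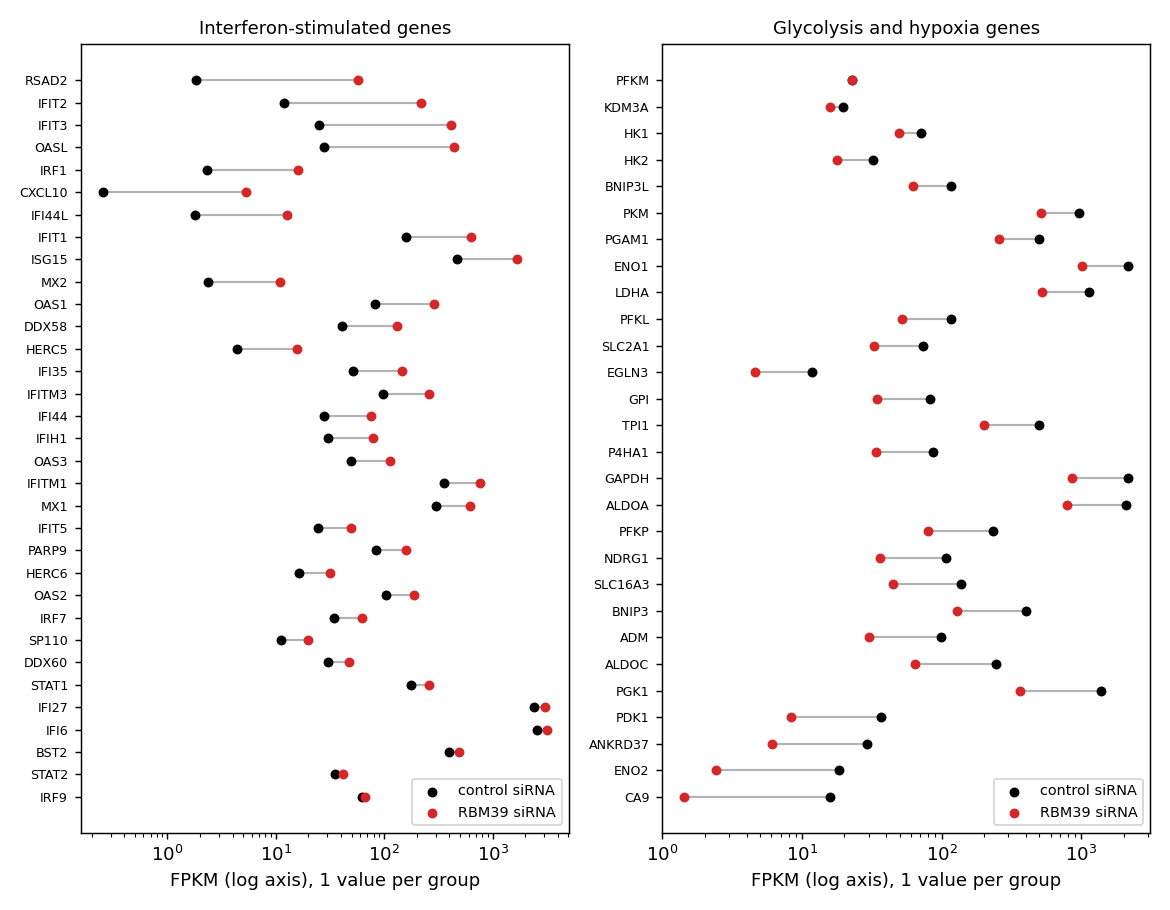
FPKM of each compared member of the interferon-stimulated list (left) and of the glycolysis and hypoxia list (right), 1 value per group on a log axis, with control siRNA in black, RBM39 siRNA in red and a grey line joining the 2 values of a gene. All 33 interferon-stimulated genes lie higher with RBM39 siRNA, and all 28 glycolysis and hypoxia genes lie lower, PFKM by less than the size of a point.

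Oestrogen-response genes were also lower as a group. Of 30 compared members, 26 were below control, 8 of them at least 2-fold, and none was 2-fold higher. The median was -0.49, below all random lists. TFF3 and STC2, a secreted glycoprotein, were 5.09-fold and 3.37-fold lower. The trefoil peptide TFF1 went from 287 to 101 FPKM, the transcription factor MYB was 2.88-fold lower and the progesterone receptor PGR 1.79-fold lower. GREB1, a receptor cofactor, stood at 58.0 and 43.6 FPKM, and the protease CTSD at 572 and 569 FPKM. The luminal identity list, which contains the oestrogen receptor gene ESR1 (19.2 FPKM in control and 11.6 FPKM in RBM39 siRNA cells), had a median of -0.17 over 20 members, inside the range of random lists. Its member ELF3, an epithelial transcription factor, was 2.80-fold higher, and the prolactin receptor PRLR was 1.71-fold lower.

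Mitotic genes were lower as a group. Of 33 compared members of the mitosis and G2/M list, 31 were below control and none differed by 2-fold, with a median of -0.46, below all random lists. UBE2C, which directs cyclin degradation, went from 142 to 74.9 FPKM, the DNA topoisomerase TOP2A from 90.0 to 51.8 FPKM and the kinase CDK1 from 122 to 74.6 FPKM. MKI67, the proliferation marker, stood at 4.28 and 4.86 FPKM. The DNA replication and G1/S list had a median of -0.08 over 38 members, inside the range of random lists, with CCNE1 (cyclin E) 2.25-fold higher and thymidine kinase TK1 1.63-fold lower. The homologous recombination and Fanconi list, at -0.10 over 24 members, was also inside, with RBBP8 1.83-fold and FANCI 1.63-fold lower.

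Apoptosis regulators, ribosome biogenesis genes and members of the COMPASS and MLL histone methyltransferase complexes were higher as lists, by less than 2-fold in the median. Apoptosis regulators had a median of 0.40, with 17 of 21 above control and 3 at least 2-fold. These were the inhibitor of apoptosis BIRC3 (5.62-fold), and the pro-apoptotic BMF (2.46-fold) and BIK (2.38-fold). Ribosome biogenesis genes had a median of 0.29, with 26 of 31 above control and none at 2-fold. UTP15 and RRS1 were 1.74-fold and 1.66-fold higher. COMPASS and MLL complex members had a median of 0.39, with 16 of 21 above control. The methyltransferases KMT2D, SETD1B and KMT2B were at least 2-fold higher on the log2(FPKM + 1) scale, KMT2D from 2.48 to 8.77 FPKM and SETD1B from 1.42 to 4.88 FPKM. KMT2A (MLL1) was 1.67-fold higher. The list was not outside the range of random lists at a mean of at least 5 FPKM, where 15 members, KMT2D among them, had a median of 0.03.

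The unfolded protein and integrated stress response list was slightly lower, with a median of -0.25 over 24 members, 16 of them below control. Its members went both ways: DDIT4, a stress and hypoxia gene that restrains mTOR, was 2.36-fold lower, and SLC3A2, the heavy chain of amino acid transporters, was 2.33-fold higher. The median moved inside the range of random lists when low values were not filtered.

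The splicing lists, which hold genes of the splicing machinery, did not stand apart. The spliceosome core and U2AF list had a median of 0.05 over 34 members, with PRPF3 2.14-fold and SF1 1.87-fold higher. The list of SR proteins, hnRNPs and their kinases had a median of 0.03 over 32 members, with CLK4 2.04-fold higher and CLK3 1.62-fold lower. These are levels of whole genes, and splice forms were not analysed here, so they do not show whether splicing itself differed. The p53 target and CDK inhibitor list had a median of 0.14 over 26 members. AEN and PMAIP1, a nuclease and an apoptosis activator, were 3.12-fold and 3.01-fold higher, and the repair gene DDB2 was 2.21-fold lower. The AP-1 and immediate early list had a median of 0.12 over 17 members, with BATF 3.80-fold and KLF4 2.35-fold higher. Cholesterol and fatty acid synthesis genes had a median of -0.01 over 31 members, with HMGCS1 1.93-fold higher and FADS2 1.71-fold lower. HOX genes had a median of 0.00 over 7 members, with HOXC11 1.52-fold and HOXC10 1.39-fold lower. Oxidative phosphorylation genes had a median of -0.16 over 40 members, with COX8A 1.74-fold and NDUFB8 1.65-fold lower. Cytoplasmic ribosomal proteins had a median of -0.16 over 65 members, with RPL12 1.92-fold and RPL32 1.74-fold lower in FPKM. This was inside the range of random lists, -0.23 to -0.05, so lists of like abundance were mostly lower too. With quantile normalization the median of the ribosomal proteins was 0.14. Basal and mesenchymal markers had a median of 0.13 over 7 members. Of the other basal keratins on this list, KRT5 stood at 0.0392 and 0.0713 FPKM and KRT14 at 0.0192 and 0.179 FPKM. VIM stood at 1.61 and 0.560 FPKM.

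**Figure D2:**
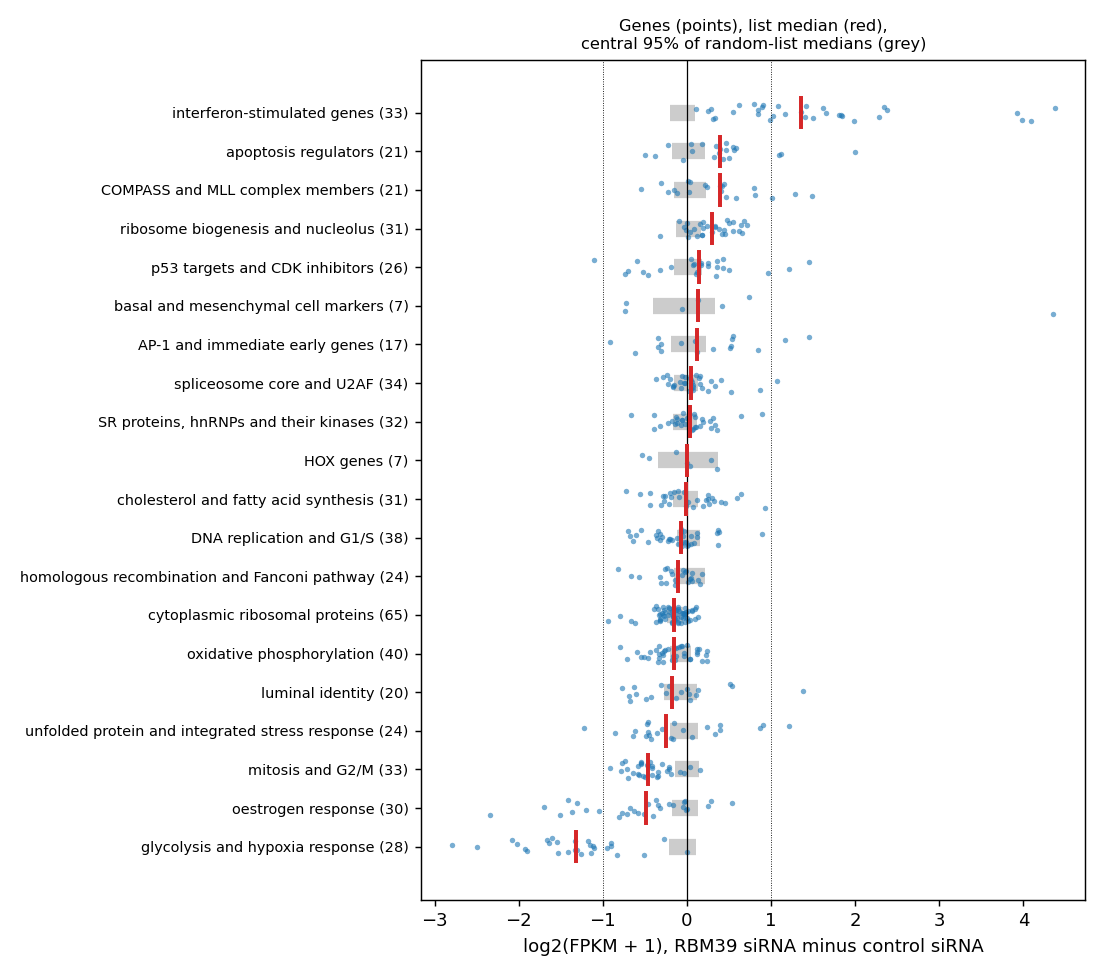
Differences of log2(FPKM + 1), RBM39 siRNA minus control siRNA, for the 20 gene lists with at least 5 compared members (number in brackets). Points are genes, red bars are list medians, grey bars hold the medians of 95% of expression-matched random lists, and dotted lines mark 2-fold; 4 lists lie above the grey range and 4 below it, with interferon-stimulated genes at 1.35 and glycolysis and hypoxia genes at -1.31 farthest out.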

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

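All tests in this part were chosen after the values were seen. Outside the named genes, 14 unnamed rows had at least 5 FPKM in the RBM39 siRNA group and were at least 2-fold above control, the highest at 502 against 83.7 FPKM. They were picked out as signal in rows that the comparisons leave out. Another 7 unnamed rows were at least 2-fold lower, 1 of them listed at 6778 FPKM in control and 0 in the RBM39 siRNA group.

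Among short genes, with a span of at most 300 bp, 11 were listed at 0 in control and at 5 FPKM or more in the RBM39 siRNA group. They were picked out as signal in a class of RNA that the rule for named genes mostly leaves out. Another 18 went the other way, among them SNORD47 (50861 FPKM in control) and SNORD14D (34657 FPKM in control), both listed at 0 with RBM39 siRNA. The tables argue against a change in transcription of the surrounding gene: for 20 of these short RNAs a containing gene was in the table, and the median absolute log2 difference of the containing genes was 0.16, with none reaching 1. SNORD32A went from 28602 FPKM to a listed 0, while RPL13A around it stood at 589 and 529 FPKM. Unstable estimates for transcripts shorter than most fragments may account for the pattern, since 33.7% of the 86 short genes at 5 FPKM or more were at 0 in the other group, against 0 of 8249 longer genes, and in both directions. A change in small RNA processing stays open as an untested biological explanation, and the very high control value of SCRIB, which contains MIR937, was not resolved.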

How the results depend on the processing

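The lower level of RBM39 (log2 difference -1.27) and the calls of 17 of the 20 gene lists stayed the same under the 11 alternatives that change the values or the genes compared, or under 10 for the HOX and the basal and mesenchymal lists, which had too few members at a mean FPKM of at least 5. The alternatives highest row, joined rows, short genes, length and GC trend and the 1.5-fold threshold, which was applied to the gene counts alone, were chosen after the data were seen. The count of genes at least 2-fold lower grew from 325 to 514 with a pseudocount of 0.1, where weak genes weigh more. At 1.5-fold, 2072 genes passed, 962 higher and 1110 lower. Apart from these settings, 205 to 353 genes were higher and 229 to 402 lower. The COMPASS and MLL list was no longer outside the range at a mean FPKM of at least 5 (median 0.03), nor was the unfolded protein and stress list without a filter (-0.19). The ribosomal protein list moved from -0.16 to 0.14, above the range, with quantile normalization; the cause was not tested. Differences correlated weakly with transcript length (Spearman's rho 0.16) and GC content (-0.10) across genes, which are not independent. Among named genes, PRTN3, VIM and CD68 moved by over 1.5 times with a pseudocount of 0.1, as did RPL12, RPL32 and COX8A with quantile normalization and COX8A with the trend removed, and none changed direction.

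No paired analysis was possible because the columns hold 1 value per group and carry no replicate letter. For the same reason the variance models, the fits without a library, camera, fry and the count tests were not run. With 1 value per group and no counts, depth and replicate error could not limit any statement by a number, so no difference here is shown to exceed the spread between libraries.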

Other observations

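All tests in this part were chosen after the values were seen. Beside the interferon-stimulated genes, the interferon genes IFNL1 and IFNB1 had more transcript in RBM39 siRNA cells. IFNL1 went from 0.711 to 15.4 FPKM, IFNB1 from 0.376 to 4.49 FPKM and the sensor TLR3 from 0.283 to 5.10 FPKM. IFNL2 (11.7 FPKM) and IFNL3 (12.7 FPKM) are near-identical copies and share reads. The receptor subunit IFNLR1 stood at 1.37 and 1.66 FPKM. A list of interferons and RNA sensors had a median log2 difference of 0.88 over the 14 of its 20 genes that were compared. Among these 14, 12 were above control, 7 of them at least 2-fold, and 2 were below. The 8 genes whose values had not been looked at when the list was drawn up had 0.66, with 1 at least 2-fold higher. Genes of MHC class I presentation had a median of 1.16 over 16 genes, and 0.99 over the 12 not looked at before, both above the central 95% of random lists. Of the 16 genes, 12 were above control, 9 of them at least 2-fold, and 4 were below. HLA-B and HLA-C have no usable value under their own symbols and were not compared. B2M, the class I light chain, went from 2109 to 4792 FPKM, the peptide transporter TAP1 from 56.6 to 157 FPKM and the transactivator NLRC5 from 2.21 to 8.18 FPKM.

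Epidermal differentiation genes had a median of 2.09 over 20 genes, but 11 of these had been noticed among the largest differences. The 9 not looked at before had 0.46, with 1 at least 2-fold higher (S100A7) and 2 at least 2-fold lower (KRT15 and CNFN). Beside KRT17, members with large differences were S100A8, S100A9 (10.9 to 147 FPKM), SPRR1A, a cornified envelope precursor (3.47 to 58.2 FPKM), and KRT16 (12.9-fold higher).

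A hypothesis was tested for the interferon-stimulated genes. The tables argue against a length or GC effect as the whole cause, since the list's median was 1.34 after that trend was removed, and against immune cells in the culture, since the highest of PTPRC, CD3E, CD14, LYZ and ITGAM was 0.124 FPKM with RBM39 siRNA. If the title WT SiRNA means a control siRNA, as taken here, sensing common to any duplex is shared by both groups. A difference in sensing between the control and RBM39 siRNA may account for the response as well as loss of RBM39 may. With 1 RBM39 siRNA column these cannot be told apart, because the column does not separate siRNA sequences or libraries. A difference in 1 of the 2 libraries behind the column is open for the same reason.

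Another hypothesis was tested for the glycolysis and hypoxia genes. A length or GC effect as the whole cause is argued against by a median of -1.26 after the trend was removed. The lower bound for 95% of expression-matched random lists was -0.21, so lists of like abundance did not fall as far. That comparison is the one that called the list lower, so it is no separate test of lower values for all abundant transcripts. Its 20 expression bins do not separate the most abundant genes from the rest of the top bin. Less HIF activity in RBM39 siRNA cells is a candidate explanation: 20 other HIF targets, none in the first list, had a median of -0.94, below all random lists, with 10 at least 2-fold lower, among them HILPDA (199 to 67.4 FPKM) and EGLN1 (27.1 to 10.5 FPKM). The mRNAs of HIF1A (41.4 FPKM in control and 66.4 FPKM with RBM39 siRNA) and EPAS1, which encodes HIF-2 alpha (4.53 and 9.08 FPKM), were higher. HIF proteins were not measured, so these mRNA levels do not decide whether HIF activity was less. A culture difference between the dishes, such as cell density or oxygen, cannot be told apart from an effect of the siRNA with 1 value column per group.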
